A study of Mus musculus with 4 samples.

How the data were processed

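Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on livers of C57BL6/J mice. The series holds 4 libraries. Of these, 2 came from livers that overexpressed MafG carrying the BLRP peptide tag (BLRP-MafG) and 2 from livers given the BLRP control. Per the labels' protocols, tissue was fixed with formaldehyde, nuclei were isolated and sonicated, and chromatin was precipitated with an antibody against the tag (an Avi-tag antibody, per the labels).

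The data analysed were 1 list of peaks for the whole series. Per the submitters' processing notes, Bowtie2 and HOMER were used and the genome build was mm10; their versions are not given in the sources used here. Per the file headers, peaks were called with HOMER findPeaks on 1 collection of BLRP-MafG tags, with 1 collection of control tags as input. The headers name no library number, so it is not known whether each collection joined both libraries of a group or held 1 of them. Peak size was set to 200 bp, peaks lay at least 400 bp apart, and the fragment length was estimated at 168 bp. At most 1 tag per bp was considered, and a false discovery rate of 0.001 corresponded to 11 tags. Per the file headers, 142591 putative peaks were reduced to 68763. Of the putative peaks, 68547 were removed for missing a 10-fold excess over control at a Poisson p of 1e-06, 5278 for missing a 4-fold excess over the surrounding 10 kb at a p of 0.0001, and 3 as too clonal.

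Of the tag signals in the list, 2 were used, as deposited. The first is the BLRP-MafG signal, which the authors scaled to 10000000 tags in total and which is called the normalized tag count below. The second is the unscaled control signal, in which 0.5 stands where there were 0 tags. The deposited fold values are linear ratios of BLRP-MafG to control, to the surroundings and to the tags expected from unique positions. The deposited fold over control counts 0 control tags as 0.5. The deposited p-values are Poisson p-values by the peak caller; they weigh tags, not animals. The deposited peak score ran from 11 to 389 and was not used further. The list holds no value per library, so no comparison between animals could be tested and no standard deviation can be given.

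The header gives 20406492 BLRP-MafG tags, of which 3435861 (16.84%) lay in peaks. The deposited fold over control, set against the tags behind it, implied 1.72e+07 control tags. Multiplied back by the stated total, 100% of the normalized tag counts came within 0.11 of a whole number of tags; these whole tags were used for exact 95% Poisson intervals of the normalized tag count and exact 95% conditional binomial intervals of the ratio to control. A ratio against 0 control tags was computed against a floor of 3 tags and is given with the lower limit of its exact 95% interval, which lies below it. A ratio against 1 control tag is given as counted and also against this floor, and only the ratios against the floor are comparable between such peaks. Intervals and floors cover counting error only. The median peak held 25 BLRP-MafG tags and 1 control tag, so the ratio of a single median peak is known only roughly. Because the list holds only peaks above the caller's limits, a gene without a listed peak may hold weaker signal, or signal that missed the required excess over control or surroundings.

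Genes were taken from an NCBI RefSeq gene table of assembly GRCm38.p6, the same assembly as mm10, with 21887 protein-coding genes on the 21 placed chromosomes. The table gives the start and end of each gene but neither strand nor exons, and no genome sequence was used here. The tests planned before the data were examined used transcription start sites, so distances are given here to the nearer end of the gene, whichever end that is. Exons and introns were not separated, and the planned motif tests were not run. All 381 genes of the 22 gene lists fixed before the data were examined were found in the table by symbol.

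A gene counted as near a peak when the midpoint of a peak lay within 10 kb of either end. Lists were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 22 lists and a threshold of 0.05. The bile acid synthesis and transport lists, the NRF2 list, and the neuronal and muscle lists were each compared by the same test with 5 joined hepatocyte lists (urea cycle and amino acids, gluconeogenesis and glycogen, secreted proteins, fatty acid oxidation, xenobiotic cytochromes P450). Lists were also compared with 10000 random lists matched on gene length and on the number of gene ends within 50 kb, each in 10 classes. Because each gene is drawn independently, the distribution of the share under this matching was also computed exactly, a step added after the data were examined. The position of peaks was compared with 1000 random placements of the same number of midpoints on the same chromosomes, between the first and the last gene or peak; assembly gaps inside that span were not excluded. Peak heights were compared by a permutation test of medians with 100000 resamples. Genes and peaks of 1 list are not replicates, so these p-values describe this list and not the spread between animals.

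Peaks were given to genes by distance alone, so 1 peak can count for several neighbouring genes. The rule for named genes was fixed before the data were examined. It names the members of the bile acid synthesis, transport and signalling lists and of the small MAF list, with values for the 20 that have the highest peaks. It adds 6 bile acid genes in any case, the 10 highest peaks near a gene, and the 3 highest members of each other list; some genes that the rule names are not reported here. Alternatives covered the window (1 kb and 50 kb), stricter sets of peaks, overlap by 1 base, whole genes, autosomes only, peaks with fewer than 10 control tags, and other placements. On simulated peaks, the Fisher test called 10 of 10 lists given an added peak at each gene and 1 of 10 lists given none, among 21887 genes. The matched lists called 10 of 10 and 0 of 10. Because every gene of the former lists had a peak, this does not show how often lists with lower shares or fewer genes would be called. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.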

Results

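The series mapped where overexpressed, tagged MafG sits on chromatin in mouse liver. No library holds tagged MafG at its native level, so the peaks may include sites that the native protein does not occupy. MafG is a small MAF protein, a basic leucine zipper factor that lacks a transactivation domain and pairs with partners such as NRF2 and BACH1. Its title frames the question as the control of bile acid synthesis and metabolism. There were 2 libraries of BLRP-MafG livers and 2 of BLRP control livers, and the deposited result was 1 list of peaks called over the control. Values come from 1 BLRP-MafG and 1 control tag collection, and it is not known whether each joined both libraries of its group. There is no value per library, and intervals below are exact 95% intervals of the tag counting alone. Depth was 20406492 tags for BLRP-MafG and an implied 1.72e+07 for the control. Positions are on the mm10 build, and peaks were given to genes by distance, so neighbouring genes can share a peak.

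BLRP-MafG gave 68763 peaks over the control, and they varied widely in height. The median normalized tag count was 12.3 per 10000000 tags, with quartiles of 7.84 and 23.5, and the highest reached 2109. The highest 1000 peaks held 16.7% of the tags in peaks. Every listed peak had passed a 10-fold excess over control and a 4-fold excess over the surrounding 10 kb, so low control counts and high folds follow in part from that filter. The control held 0 tags in 30505 peaks (44.4%) and 10 or more in 71. In the authors' deposited table the median fold over control, with 0 control tags counted as 0.5, was 24.2, and 44182 peaks (64.3%) reached a fold of 20. Counting error limited single peaks: 10459 peaks (15.2%) had a lower bound of the ratio above 10. In the authors' deposited table the median fold over the surrounding 10 kb was 16.2.

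Peaks were concentrated near genes, although most lay away from gene ends. Of the 68711 peaks on placed chromosomes, 5336 (7.77%) lay within 1 kb of an end of a protein-coding gene, 2.52 times the 3.09% ± 0.0650 (SD of 1000 placements) at random positions. Within 10 kb of a gene end lay 31.1%, against 21.4% at random. A further comparison put 44.1% of peaks inside a gene and over 1 kb from any gene end, against 38.5% at random. Outside genes and over 1 kb from any gene end lay 48.1%, against 58.4% at random. Each of these 4 differences had an adjusted p of 0.000999 by permutation of positions, the smallest that 1000 placements can give. Random positions could fall in assembly gaps, where no peak can lie, and were not matched on mappability. In another placement, each peak was shifted by up to 500 kb, which keeps it in its neighbourhood. The excess inside genes and over 1 kb from any gene end then became a deficit (44.1% against 44.7%, adjusted p = 0.004975 by permutation of positions, the smallest that 200 placements can give). The excess within 1 kb of gene ends held at 1.96 times. Peaks near gene ends, farther inside genes and farther outside genes add up to all peaks. That deficit can thus follow from the excess at gene ends, and the share of all peaks inside genes was not computed. Under the same shift the excess within 10 kb of a gene end shrank from 9.74 to 4.48 percentage points. The difference outside genes and over 1 kb from any gene end shrank from -10.3 to -3.23.

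Peaks close to gene ends were lower than the rest. Their median normalized tag count was 10.8 (quartiles 7.84 and 16.7) in 5336 peaks, against 12.3 (quartiles 7.84 and 24.5) in 63375 others (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Among the highest 1000 peaks, 26 (2.6%) lay within 1 kb of a gene end, against 3.14% at random positions, a difference within the spread of the placements (adjusted p = 0.378 by permutation of positions). Among the 34355 lowest peaks the share was 9.04%.

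Chromosome X carried fewer peaks per length than any autosome. Its density was 9.33 peaks per Mb, against 27.5 over all autosomes and a range from 23.8 on chromosome 14 to 33.8 on chromosome 11. The median normalized tag count was 9.31 on X. Chromosome Y held 215 peaks, or 2.37 per Mb.

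**Figure D1:**
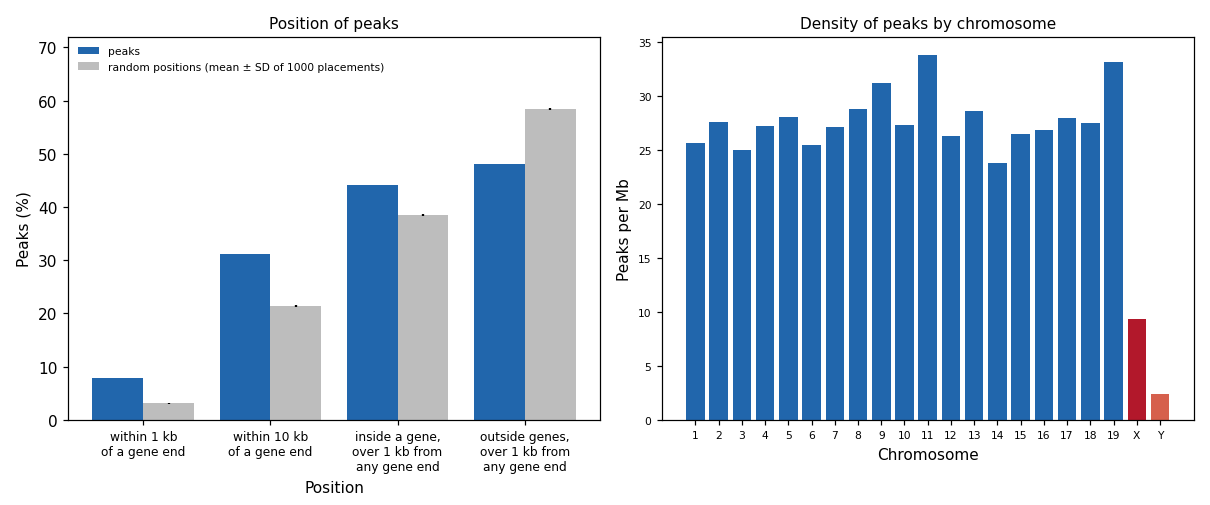
Left, share of the 68711 placed peaks (%) in each position class (blue) beside random positions (grey, mean ± SD of 1000 placements). Right, peaks per Mb on each chromosome. The share within 1 kb of a gene end was 7.77% against 3.09% at random, and X held 9.33 peaks per Mb where autosomes held 23.8 to 33.8.

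Genes that convert cholesterol to bile acids mostly had a peak nearby, but of ordinary height. Of 21 synthesis genes, 19 (90.5%, interval 69.6% to 98.8%) had a peak within 10 kb of an end, against 69.2% of other protein-coding genes. This did not pass Fisher's exact test after adjustment over the 22 lists (p = 0.0337, adjusted p = 0.103). Over 10 alternative settings the excess ran from 2.70 to 21.3 percentage points, and 0 of them passed adjustment. The lowest came with a fold of at least 20 over control, where 12 of 21 genes had a peak. The median highest normalized tag count of the list was 13.7, against 11.8 in matched random lists (permutation, adjusted p = 0.852). The highest was a peak of 691 (655 to 728) at chromosome 2:126591408-126591608, which lies 3265 bp outside Slc27a2, an acyl-CoA synthetase gene, and closer to the histidine decarboxylase gene Hdc. The control held 11 tags there, a ratio of 108 (60.2 to 217). Cyp39a1, an oxysterol hydroxylase gene, held a peak of 135 (119 to 152) inside it at chromosome 17:43743955-43744155, and Ch25h, the cholesterol 25-hydroxylase gene, had one of 40.7 (32.4 to 50.4) 1955 bp outside it. Hsd3b7 had one of 29.9 (22.9 to 38.4) 301 bp inside one end.

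The P450 enzymes of bile acid synthesis had peaks of different heights. Cyp27a1, which starts the acidic pathway, held a peak of 28.4 (21.6 to 36.7) at chromosome 1:74719359-74719559 inside the gene, with 1 control tag and a ratio of 48.9 (8.44 to 1965), or 16.3 against a floor of 3 control tags. Cyp8b1, the sterol 12α-hydroxylase of cholic acid synthesis, had none inside the gene. The only peak within 10 kb of it lay 7817 bp away at chromosome 9:121924022-121924222, with a tag count of 18.6 (13.2 to 25.6) and a ratio of 10.7 (3.39 to 54.1), and a peak of 21.1 lay 10660 bp away on the other side. Cyp7a1, the rate-limiting enzyme of the classical pathway, had 2 low peaks within 10 kb. The higher, of 7.84 (4.48 to 12.7), lay 2567 bp outside the gene at chromosome 4:6262945-6263145, with 1 control tag and a ratio of 13.5 (2.10 to 566), or 4.50 against the same floor, and one of 6.37 lay 216 bp outside its other end. Cyp7b1 held 5 peaks within its length. One of 7.84 (4.48 to 12.7) lay 8140 bp inside one end, and the highest, of 24, lay farther inside at chromosome 3:18096884-18097084. The tag count intervals of Cyp7a1 and Cyp27a1 did not overlap, whereas the intervals of their ratios to control did. Baat and Cyp2c70 had no listed peak within 10 kb. The other synthesis genes with one were Cyp46a1, Akr1d1, Akr1c6, Akr1c14, Amacr, Acox2, Hsd17b4, Scp2, Slc27a5, Acot8 and Abcd3.

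Among bile acid and biliary lipid transporters, 14 of 16 genes (87.5%, interval 61.7% to 98.4%) had a peak, which did not pass Fisher's exact test against other genes (adjusted p = 0.293). Slc10a1, the gene of the sinusoidal bile acid uptake carrier NTCP, had 5 peaks within 10 kb of its ends. The highest, of 27 (20.3 to 35.1), lay 4736 bp outside it at chromosome 12:80973341-80973541, with a ratio of 11.6 (4.28 to 44.1). The highest of the list stood 6759 bp outside Slco2b1 at chromosome 7:99717999-99718199, at 144 (128 to 161). Abcc2, Abcc3 and Slco1a4 had peaks of 49 (39.9 to 59.6), 32.8 (25.4 to 41.7) and 29.9 (22.9 to 38.4). Abcb11, the bile salt export pump, had a low one of 9.31 (5.61 to 14.5), 403 bp outside the gene at chromosome 2:69342919-69343119, with 0 control tags and a ratio of 5.34 against the floor of 3 tags (exact lower limit 3.94). Slc51a and Atp8b1 had none within 10 kb, and Slc10a2, Abcc4, Slco1a1, Slco1b2, Slc51b, Abcb4, Abcg5 and Abcg8 had peaks of 25 or lower.

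Several regulators of bile acid synthesis had tall peaks, but as a list their heights did not pass adjustment. Of 14 genes, Mafg among them, 12 had a peak (adjusted p = 0.395 by Fisher's exact test). Their median highest normalized tag count, genes without a peak at 0, was 27.7. That was above 99.5% of random lists matched on gene length and neighbours, whose median was 11.6, with a permutation p = 0.0106 over matched lists and an adjusted p = 0.117. Without Mafg the median was 27.4 (permutation p = 0.0168). By the same comparison, urea cycle and amino acid genes stood above 99.7% and NRF2 antioxidant genes above 99.2% of matched lists. Neither passed adjustment (permutation, adjusted p = 0.117 and 0.120). Nr1h4, which encodes the bile acid receptor FXR, had a peak of 138 (123 to 155) 8414 bp outside the gene at chromosome 10:89541959-89542159, with 0 control tags. Its ratio to control was 79.3 against the floor of 3 tags, with an exact lower limit of 64.1. The receptor genes Rxra, Hnf4a and Nr1i3 had peaks of 88.2 (75.8 to 102), 44.1 (35.5 to 54.2) and 31.9 (24.6 to 40.6). The last lies near several genes, among them Apoa2. Klb, Fgf15 and Fgfr4, the co-receptor, ligand and receptor of the intestinal FGF signal, had peaks of 30.4 (23.3 to 38.9), 27.9 (21.2 to 36.2) and 27.4 (20.7 to 35.6). Nr0b2, Nr5a2, Nr1i2 and Vdr had lower ones, and Rxrb and Gpbar1 had none.

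**Figure D2:**
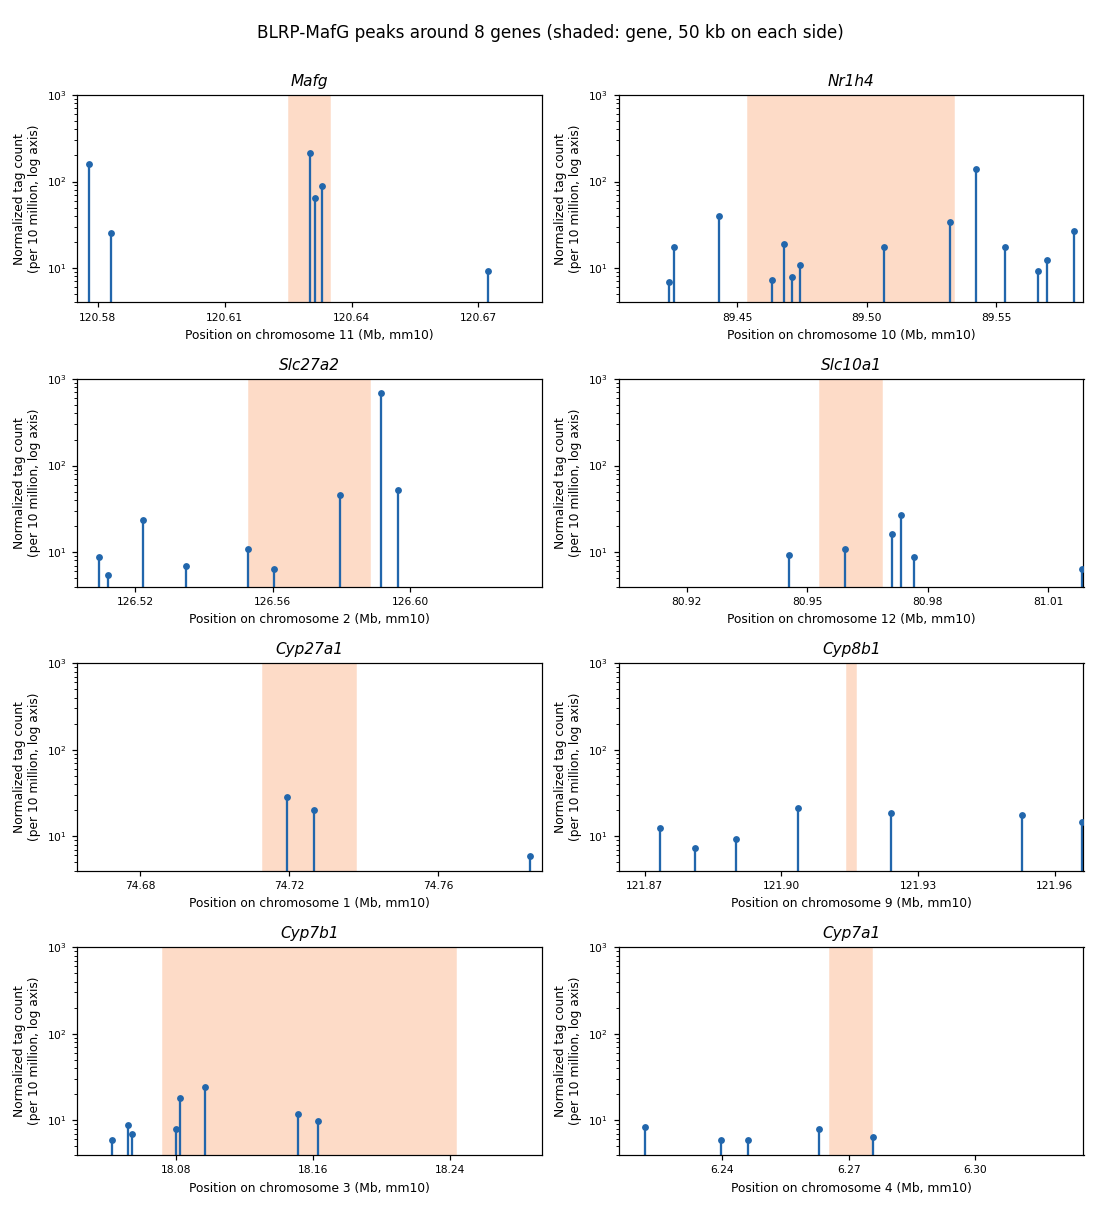
Peaks around 8 bile acid and regulator genes, with the position on the mm10 chromosome (Mb) on the horizontal axis and the normalized tag count per 10000000 tags on a log axis; each stem is 1 peak and shading marks the gene. Mafg holds 3 tall peaks up to 213, whereas no peak within 50 kb of Cyp7a1 exceeds 8.33.

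In the list of small MAF proteins, their CNC partners and Keap1, whose product represses NRF2, all 10 genes had a peak within 10 kb (100%, interval 69.2% to 100%), without passing adjustment (p = 0.0376 by Fisher's exact test, adjusted p = 0.103). Within 1 kb the count was 2 of 10. Mafg itself held 3 peaks inside the gene. They reached 213 (194 to 234) at chromosome 11:120630125-120630325, 64.7 at 120631255-120631455 and 89.7 at 120632888-120633088. The control held 1 or 2 tags at each. The overexpressed construct itself carries Mafg coding sequence, so tags at this gene can come from the construct as well as from the chromosome. Nfe2l2, which encodes NRF2, held a peak of 90.7 (78.1 to 105) at chromosome 2:75695905-75696105, and Nfe2l3 one of 73.5 (62.2 to 86.3). Maff, Mafk, Nfe2, Nfe2l1, Bach1, Bach2 and Keap1 had peaks of 26.5 or lower.

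NRF2 antioxidant genes were near peaks more often than other genes. Of 38, 36 (94.7%, interval 82.3% to 99.4%) had a peak, against 69.2% of other genes (Fisher's exact test, adjusted p = 0.00603), and the difference, of 25.6 percentage points, was 20.5 against matched random lists (74.2%, adjusted p = 0.0440 by permutation and 0.0431 by the exact distribution), though by a narrow margin. Hmox1, the haem oxygenase 1 gene, had 6 peaks within 10 kb of its ends, the highest, of 316 (292 to 341), 9635 bp outside it at chromosome 8:75083883-75084083. The glutathione S-transferase genes Gsta3 and Gstm4 held peaks of 184 (166 to 203) and 141 (125 to 158). Both belong to families of similar copies, whose reads the mapping could have split. Slc7a11 and Cbr3 had no peak within 10 kb. The call was lost with a window of 50 kb, in which 93.4% of all genes have a peak, and with the highest 1000 peaks only.

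Haem and iron genes (18 of 21, adjusted p = 0.281) and proteasome subunits (26 of 31, adjusted p = 0.164) did not pass Fisher's exact test at 10 kb. Within 1 kb of a gene end both did by the same exact test, with 12 of 21 (adjusted p = 0.00778) and 17 of 31 (adjusted p = 0.00328), against 24.5% of all genes. The haem transporter gene Slc48a1 held a peak of 281 (258 to 305), and the transferrin gene Trf had one of 102 (89 to 117) outside it. Among the proteasome ATPase genes, Psmc1 held a peak of 180 (162 to 200), and Psmc6 and Psmc3 had peaks of 82.3 (70.3 to 95.8) and 39.7 (31.5 to 49.3) outside them.

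The 2 fatty acid lists and the clock list were complete. All 19 fatty acid oxidation genes (adjusted p = 0.0190), all 16 fatty acid and triglyceride synthesis genes (adjusted p = 0.0261) and all 16 core clock genes (adjusted p = 0.0261) had a peak, by Fisher's exact test against other genes. Their excess, of 30.8 percentage points over other genes in each list, was 24.4, 22.6 and 23.0 over matched random lists in the same order (permutation, p = 0.0106, 0.0330 and 0.0248), which did not pass adjustment (adjusted p = 0.117, 0.181 and 0.181), and none of the 3 calls held with the stricter fold of 20 over control. Within 1 kb of a gene end, by the exact test, the excess was all but gone for clock genes (4 of 16, 0.452 points, adjusted p = 1) and not called for fatty acid oxidation (7 of 19, adjusted p = 0.518), while fatty acid synthesis passed (9 of 16, adjusted p = 0.0240). Malic enzyme Me1, the elongase Elovl6 and ATP citrate lyase Acly held peaks of 126 (111 to 142), 81.3 (69.4 to 94.7) and 57.8 (47.9 to 69.2). Acadl, an acyl-CoA dehydrogenase gene, held one of 122 (107 to 138), and Slc25a20 and Acadvl had 61.3 (51 to 73) and 42.6 (34.1 to 52.6). Per2, a repressor of the clock, held a peak of 221 (201 to 242), while Nr1d1 and Cry1 had 42.1 (33.7 to 52) and 31.4 (24.2 to 40). Cholesterol synthesis and uptake genes did not pass Fisher's exact test (18 of 23, adjusted p = 0.658). Nsdhl and Ebp had peaks of 74 and 39.7, while Idi1, Mvd and Srebf2 were among the members with none within 10 kb.

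Of the other hepatocyte lists, 3 had high shares that did not pass adjustment. All 12 gluconeogenesis and glycogen genes (adjusted p = 0.0993), 14 of 15 urea cycle and amino acid genes (adjusted p = 0.119) and 20 of 23 genes of secreted proteins (adjusted p = 0.158) had a peak, by the same Fisher's exact test. Xenobiotic cytochromes P450, with 9 of 12 (75%, adjusted p = 0.802 by the exact test), stood close to the 75.4% of their matched random lists. By the exact test within 1 kb of a gene end, the urea cycle list (9 of 15, adjusted p = 0.0161) and the secreted protein list (14 of 23, adjusted p = 0.00251) passed. The serine dehydratase gene Sds held a peak of 402 (375 to 431), and the urea cycle genes Asl and Ass1 had 140 (124 to 157) and 86.2 (74 to 100) outside them. Tat and Pck1 had peaks of 106 and 85.3, Alb and Serpinc1 of 126 and 62.2, and Cyp1a1 and Cyp1a2 shared one of 101.4, with Cyp3a11 at 30.9. In the acute phase and interferon list (15 of 20, adjusted p = 0.809 by Fisher's exact test), Lcn2 had a peak of 269, Ifit3 of 152 and Saa1 of 61.3.

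Set against these hepatocyte genes, no difference was detected for bile acid genes. Of 37 bile acid synthesis and transport genes, 33 (89.2%) had a peak, against 74 of 81 (91.4%) genes of the 5 hepatocyte lists (Fisher's exact test, two-sided, p = 0.739, odds ratio 0.782 with an interval of 0.184 to 3.90). For NRF2 antioxidant genes (36 of 38), none was detected against 73 of 80 hepatocyte genes either (Fisher's exact test, p = 0.716, odds ratio 1.72, interval 0.306 to 17.8). These intervals are wide and leave room for differences in both directions, and the direction for bile acid genes turned in 3 of 9 alternative settings.

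Genes of neurons and striated muscle were near peaks less often than hepatocyte genes. Of 40, 22 (55%) had a peak, against 74 of 81 (91.4%), with an odds ratio of 0.118 (interval 0.0367 to 0.342; Fisher's exact test, p = 8.37e-06, adjusted p = 2.51e-05 over 3 comparisons). With a window of 50 kb the difference was lost (-0.0309 percentage points, exact p = 1), and among the highest 1000 peaks its direction turned (3.77 points, exact p = 0.254). Against all genes by Fisher's exact test, neither the muscle list (9 of 20, adjusted p = 0.0993) nor the neuronal list (13 of 20, adjusted p = 0.778) passed. Members with tall peaks existed all the same. Ttn, the titin gene, held one of 853, Ryr1 of 331 and Tnnt2 had one of 135, and Grin1 and Dlg4 had 49 and 42.6, the last shared with Acadvl. No list of markers of other liver cells passed the test against all genes. By Fisher's exact test the counts were 8 of 14 for macrophages (adjusted p = 0.565), 8 of 10 for endothelial cells (adjusted p = 0.802), 6 of 10 for stellate cells and fibroblasts (adjusted p = 0.658) and 5 of 8 for bile duct cells (adjusted p = 0.802). C1qa, C1qb and C1qc shared a peak of 84.8. Cdh5, Stab1 and Eng had peaks of 180, 55.4 and 43.6, Col1a1, Acta2 and Pdgfrb of 70.6, 44.6 and 35.8, and Sox9, Spp1 and Aqp1 of 106, 38.2 and 23.5.

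**Figure D3:**
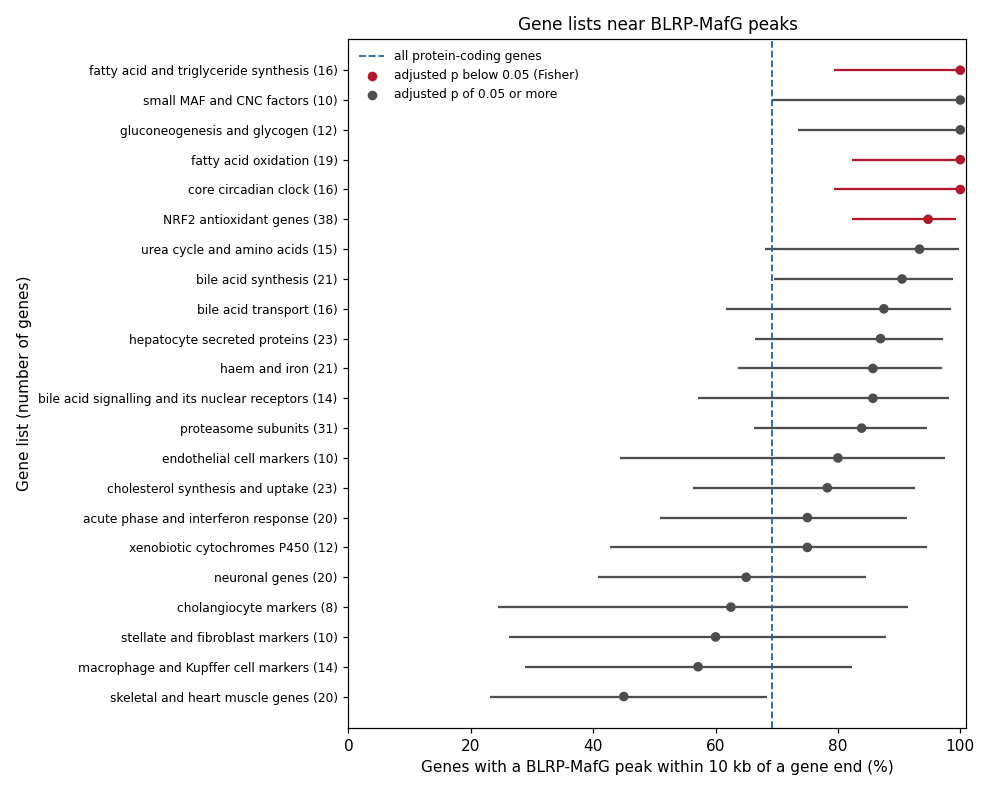
Share of the genes of each list (%) with a peak within 10 kb of a gene end; bars are exact 95% binomial intervals, the dashed line marks all protein-coding genes (69.2%), and red marks an adjusted p under 0.05 by Fisher's exact test. The NRF2, fatty acid and clock lists lie to the right of the line, and muscle genes (45%) lie farthest to the left.

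Of the 10 highest peaks near a protein-coding gene, those at Ttn and near Slc27a2 belonged to genes of the lists. The highest stood inside Sfi1 at chromosome 11:3133503-3133703, with a tag count of 2109 (2046 to 2173) but also 60 control tags, where placed peaks held a mean of 1.00. The others were at or near Ttn (853), Got1l1 (728), Ptx4 (705), Hdc (691, the peak also near Slc27a2), Zfp9 (667), Coro6 (652), the peroxisomal acyl-CoA oxidase gene Acox3 (619), Tfcp2l1 (574) and Cradd (527). Control tags at these other 9 peaks ran from 0 to 11. The peak at Got1l1 had 0 control tags and a ratio of 418 against the floor of 3 tags (exact lower limit 339).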

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

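Peaks outside the 21 placed chromosomes entered no comparison and were not tested; like every listed peak, they had to pass a 10-fold excess over control. The list holds 51 peaks on unplaced contigs, with a median normalized tag count of 20.1 against 12.3 on placed chromosomes. The highest of them, at 2044 on contig JH584304, had 62 control tags, and another on the same contig, at 673, had 39. The mitochondrial genome held 1 peak, at 5199-5399, with a normalized tag count of 55.4 and 5 control tags.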

How the results depend on the processing

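The tests with whole genes, gene lists on autosomes only, peaks with fewer than 10 control tags, shifted peaks, genes of every biotype, either gene end in place of a transcription start, the lower bound of the ratio, the list without Mafg, the relaxed limits for clusters of tall peaks and the exact matched distribution were chosen after seeing the data. No paired analysis was possible because the peak list holds no value per library; for the same reason edgeR, DESeq2 and leaving out replicates were not run. The file assigns no gene to a peak and no genome sequence was used, so that assignment, the GC-matched placement and the motif tests were not run. Of the 68763 peaks, 44182 had a fold of at least 20 and 10459 a lower bound of the ratio above 10. Merging within 100 bp left 68763, an outcome fixed in advance by peaks of 200 bp set at least 400 bp apart. The 4 lists called became 6 at 1 kb (2 of the 4 kept; fatty acid oxidation and clock genes lost), 0 at 50 kb (0 with unadjusted p under 0.05 by Fisher's exact test), 3 in the 34355 highest peaks (2 kept), 1 at a fold of 20, 0 in the 1000 highest peaks (2 unadjusted), 1 with whole genes, 2 on autosomes and 1 against matched lists. NRF2 genes were called in 8 of 10 alternatives (adjusted p from 0.000202 to 0.880), fatty acid synthesis in 4, fatty acid oxidation in 3 and clock genes in 2. The difference between bile acid and hepatocyte genes, of -2.17 percentage points, turned to 2.47 at 50 kb, 1.47 in the 1000 highest peaks and 0.534 with whole genes. It widened to -9.08 at 1 kb, -12.1 in the 34355 highest peaks and -15.6 at a fold of 20, and passed no threshold (p from 0.117 to 1). That between non-liver and hepatocyte genes, of -36.4 points, held in 7 of 9 alternatives. By Fisher's exact test it was -0.0309 at 50 kb (p = 1), where nearly all genes have a peak, and 3.77 in the 1000 highest peaks (p = 0.254); the cause of the latter, and of the turns in the bile acid difference, was not tested. The share of peaks within 1 kb of a gene end, 4.68 points above random, was 0.544 below (-0.544, adjusted p = 0.378 by permutation) in the 1000 highest peaks. The share inside genes and over 1 kb from any gene end, 5.60 points above, was -0.582 with shifted peaks, whose random positions stay in gene-rich neighbourhoods.

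Directions of single lists against all other genes also turned, in percentage points; none passed the threshold, and the cause was not tested. At 1 kb they were -3.12 for bile acid signalling, -4.55 for small MAF factors and 13.0 for cholangiocyte markers. At 50 kb they were -10.05 for xenobiotic cytochromes P450, 6.63 for both cholangiocyte and neuronal genes, and 1.63 for muscle. In the 34355 highest peaks, macrophage and stellate markers both stood at 4.69. At a fold of 20, endothelial, stellate and cholangiocyte markers stood at -4.45, 5.55 and 8.06. In the 1000 highest peaks, bile acid transport, cholesterol, both fatty acid lists, gluconeogenesis, secreted proteins and xenobiotic cytochromes P450 all stood at -1.70, with 0 members near a peak, and muscle at 8.31. With whole genes, stellate and neuronal genes both stood at 5.52, and against matched lists xenobiotic cytochromes P450 stood at -0.428. Peaks of the list hold at least 9 tags and passed the required excess over control and surroundings. Genes without a peak may thus hold weaker binding, or signal that these filters removed.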

Other observations

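The tests of gene families, of dense stretches, of the vector, of relaxed limits for tall peaks and of the exact matched distribution were chosen after the results were seen. The gene list comparisons were planned, but what each explanation predicts for them was worded afterwards; the tests of chromosome X and of clusters of tall peaks were worded before their values were computed.

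Gene families named by their symbols differed in how often a peak lay within 10 kb. All 22 glutathione S-transferase genes had one (100%), as did 308 of 375 solute carriers (82.1%) and 35 of 40 genes with Nduf symbols, mostly of respiratory complex I (87.5%), against 69.0% to 69.2% of other genes (Fisher's exact test, adjusted p = 0.00153, 5.24e-08 and 0.0198 over 12 families). Sensory receptor families of other tissues stood far below. Of 1110 olfactory receptor genes, 304 (27.4%) had a peak (exact test, adjusted p = 5.92e-190), and of 355 vomeronasal receptor genes, 89 (25.1%, adjusted p = 6.63e-66). Hox genes, which pattern the embryo, had 16 of 39 (41.0%, exact test, adjusted p = 0.00102). These 6 families also differed from random genes matched on length and neighbours, which had a peak in 72.7%, 76.2%, 66.5%, 39.2%, 46.2% and 69.4% in that order (permutation over 1000 matched lists, adjusted p of 0.0137 or lower). Ribosomal protein genes (72 of 97) were not called against all genes by the exact test (adjusted p = 0.351) but exceeded their matched genes (74.2% against 59.7%, adjusted p = 0.00799), while zinc finger genes (290 of 397, adjusted p = 0.126), serpins (45 of 63, 0.785), keratins (31 of 53, 0.126) and UDP-glucuronosyltransferases (19 of 22, 0.126) were called in neither. Major urinary protein genes (10 of 22) were called against all genes by the exact test (adjusted p = 0.0352) and not against matched ones (45.5% against 45.1%, adjusted p = 1). Several of these families hold near-identical copies, among which mapping can split or drop reads, which was not tested. Both tests treat genes as independent, although neighbouring members of a family can share a peak. The p-values thus overstate the evidence for families that lie in clusters. Among fixed 100 kb stretches, the densest held 16 peaks and overlapped Abat, the gene of GABA transaminase, on chromosome 16.

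The 3 tall peaks inside Mafg form a pattern that few genes show. Their lowest had a tag count of 64.7 and they lay within 2763 bp; among 21887 protein-coding genes, 1 held 3 peaks of that height within that length, and it was Mafg. These limits were drawn around Mafg itself. At 0.5 of the height and 2 times the length, 9 genes (0.0411%) held 3 such peaks, and at 5 times the length 19 (0.0868%), Mafg included. That argues against the reading that peaks this tall cluster at many genes. A candidate explanation is reads from the Mafg sequence of the adenoviral vector, which may map to the exons of the gene. Within 10 kb outside the gene, 0 peaks reached 0.5 of that height. This cannot decide the question, because vector reads would not exclude a tall peak beside the gene. The same would also be seen if MafG bound sites within its own gene. The vector and binding cannot be told apart, since exon positions and reads were not used here, and binding itself was not tested.

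Chromosome X held 0.339 times the autosomal density of peaks. If each cell carried 1 copy of X beside 2 of each autosome, heights on X would be lower by that factor, and the density at a tag count of at least 10 on X should equal that at 20 or more on autosomes; the ratio was 0.508 (exact interval 0.471 to 0.547), which argues against copy number as the whole cause. Fewer genes per length on X (5.66 against 8.50 per Mb) is argued against as the whole cause too, since 42.4% of 966 X genes had a peak within 10 kb, against 71.2% of 20665 autosomal genes (Fisher's exact test, p = 1.74e-73). Copy number and gene density were each tested alone, so a joint effect of them stays open. A difference in mappability and a lower occupancy of X chromatin stay open too, and none of these was tested. The sex of the mice is not in the labels used here.

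Why some lists stood near peaks more often may be a matter of gene length and density. For NRF2 antioxidant genes the matched lists argue against this (permutation, adjusted p = 0.0440, and 0.0431 by the exact distribution). The margin is narrow, and the matched draws treat genes as independent, although neighbouring members of a list can share a peak. For the fatty acid and clock lists this explanation stays open. Their excess of 30.8 percentage points shrank only to between 22.6 and 24.4 over matched lists, but did not pass adjustment (lowest adjusted p = 0.117 by permutation). These lists of 16 and 19 genes are complete, so no higher share was possible, and the lost call is no evidence for gene length and density. Another candidate explanation is that peaks occur at the same rate near any gene the liver uses. The odds ratio of NRF2 antioxidant genes against other hepatocyte genes was 1.72, with an interval of 0.306 to 17.8. That interval neither requires nor excludes an equal rate, because 38 and 80 genes at shares above 90% leave little room to differ. The bile acid lists were not called, so their odds ratio of 0.782 (interval 0.184 to 3.90) cannot decide this for the called lists. No such comparison was made for the fatty acid and clock lists, and the hepatocyte genes include the fatty acid oxidation list.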
